A study of Rattus norvegicus with 16 samples.

How the data were processed

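RNA from the dorsal horn of the rat spinal cord was profiled in normal rats and in rats with cancer-induced bone pain (CIBP, called bone cancer pain here). The 16 samples comprised 12 libraries for ac4C (N4-acetylcytidine, an acetylated form of cytidine in RNA) and 4 libraries of a second RNA immunoprecipitation (RIP) in bone cancer pain. Each ac4C replicate paired an immunoprecipitated (IP) library with its input, giving 3 control and 3 bone cancer pain pairs that the labels describe as biological replicates. The peak lists of the bone cancer pain group carry the abbreviation CFA while the labels say CIBP; the groups here follow the labels, and every comparison with controls rests on that reading. The RIP had 2 IP and 2 input libraries. The target of the RIP antibody is not given in the sources used here.

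Per the submitters' processing notes, the tools were cutadapt 2.5, HISAT2 2.1.0, HOMER 4.10.4, featureCounts 1.6.3 and DESeq2, with the rn6 build of the rat genome; the notes assign no role to each tool. The peak caller is not given in the sources used here. Per the file headers, the authors' ac4C data were 6 peak lists, 1 per IP and input pair, so peaks were called per replicate pair. Whether a replicate is a single rat or several is not given in the sources used here. Each peak had a gene identifier, a strand, exon blocks, a fold enrichment (a ratio of IP over input) and log10 values of a p-value and of a false discovery rate (FDR), all deposited by the authors. The ratio is the authors' own value for each peak. It was used to describe, rank or filter peaks within a list, and its median per list was compared between groups. For the RIP, the deposited table gave per gene the authors' log2 fold of IP over input, a p-value and an FDR. It also gave 4 normalised signal values per gene, 1 per library, of a unit that the authors' header does not state. Every gene of that table had a log2 fold above 1 and a p-value of at most 0.0488, so it held only genes past a threshold, and no test of IP against input was run here. The authors' log2 fold equalled log2 of the ratio of mean IP to mean input signal to within 0.0883 for all 8671 genes.

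Read totals per library were not given in the files used, so the depth behind a peak or a signal value is unknown. In the RIP table, values of 96 small RNA genes were examined for steps of whole reads. At whole numbers up to 12 and a tolerance of 2e-05, 54 of the 96 genes placed the value of 1 read in input 1 at 1.09 times that in input 2. For the IP libraries, 20 genes gave a ratio of 0.983. Between the kinds of library, 32 genes placed 1 read of input 1 at 0.157 times that of IP 1. For input 2 against IP 2, 24 genes gave a ratio of 0.169. The next best ratios were held by nearly as many genes (50 genes at 0.547 for the inputs, 18 genes at 1.97 for the IP libraries), so depths are uncertain by small whole factors, within and between the kinds of library.

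Gene symbols came from the RIP table, which paired 8645 identifiers with a symbol; 29 symbols shared by 81 identifiers were left out of list membership. The gene table supplied with the data (assembly GRCr8) holds no Ensembl identifiers and was not used for names. Genes with a peak but without a row in the RIP table stayed unnamed, and Nat10, the enzyme that makes ac4C, was among the genes without a row, so its peaks were not analysed here. Peak location by transcript region and sequence motifs in peaks need an rn6 genome and annotation and were not analysed here.

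All peaks as deposited were the main data. A gene counted as gained with a peak in at least 2 of 3 bone cancer pain lists and in 0 of 3 control lists, and as lost in the opposite case. Numbers of peaks and genes and the medians of fold, -log10 of the p-value and exonic width were set side by side with two-sided exact permutation tests on log2 values, which cannot go below 0.10 with 3 against 3. Counts of gained and lost genes were also made for all 10 splits of the 6 lists into 3 and 3. Peaks overlapped when their exon blocks shared at least 1 bp on the same strand. Fixed gene lists (20 of pathways and 15 of cell type markers) were tested by Fisher's exact test with Benjamini-Hochberg adjustment. The design named all annotated genes as the background; without an rn6 annotation the background was the named genes of the RIP table. For the overlap of RIP genes and peak genes the design named the annotated protein-coding genes, and genes with a peak in any list took their place. In the RIP table, the median log2 fold of a list was ranked among 10000 random lists of equal size matched in 20 bins of mean input signal; this percentile describes these libraries and is no test of replicates. Matching on the mean of all 4 libraries was run first; it was replaced after its results were seen, because that mean contains the IP signal itself, and it is given where it differs.

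Named genes followed a rule fixed before the data were examined. Gained and lost genes were ranked by number of lists and then by the mean within-list percentile of the strongest peak, 10 per direction. The 10 genes in the most lists, the 10 RIP genes with the smallest FDR, and the 10 with the largest log2 fold among genes above the median of mean signal followed, with examples from the fixed lists. Placeholders, pseudogenes and unnamed loci were passed over, and a few genes that the rule selected are not reported here.

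Alternatives fixed before the data were examined were a fold of at least 4, the strongest 1173 peaks of each list (the length of the shortest list, ranked by p-value and then fold, an order chosen after seeing the data), each replicate left out in turn, a replicate block, a peak in all 3 lists, merged regions in place of genes, a reciprocal overlap of 50%, a RIP log2 fold of at least 2 and pseudocounts of 1 and 0.1. An FDR of at most 0.05 was added after seeing the data, alone, with a list left out, with 3 of 3 against 0, and as the background of the RIP overlap. The counting of gained and lost genes was tested on simulated lists of 3805 genes, where 98.5% of planted gained genes and 95.5% of planted lost genes came back. These genes were planted in nearly every list of 1 group and in none of the other, so this checked the counting and not the power to find weaker differences. The percentile of RIP lists was tested on the 8671 genes, with folds shuffled among them. There, 44 of 50 lists shifted by 0.5 log2 units and 2 of 50 unshifted lists lay above the central 95% of random lists. That check matched on the mean of all 4 libraries and drew fewer random lists. It therefore did not test the matching on input signal, nor lists whose members vary together. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and bedtools 2.31.1.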

Results

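The data described acetylated RNA (ac4C) in the spinal dorsal horn, the first relay of pain signals from the body, in 3 control and 3 bone cancer pain replicates of rat. The groups follow the labels; the bone cancer pain peak lists themselves carry the abbreviation CFA, also used for an inflammatory pain model, and this was not resolved here. A separate RIP described RNAs precipitated from the dorsal horn in bone cancer pain, in 2 IP and input pairs. The ac4C lists held 1208, 1802 and 1418 peaks in the controls and 50417, 2416 and 1173 peaks in bone cancer pain (replicates 1, 2 and 3). They named 1113, 1573 and 1256 genes in the controls and 29130, 2022 and 1078 genes in bone cancer pain. The RIP table held 8671 genes, 8420 of them protein-coding. Coordinates are those of rn6, and read depth is unknown for all libraries.

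Across both groups, few genes had a peak in every list. A gene counted wherever along it a peak lay, and transcript length was not analysed here. At an FDR of at most 0.05, an added limit chosen after seeing the data, 14 genes had a peak in all 6 lists and 9 of them were named. Among these were Slc35e2b, Usp34 (a deubiquitinase), Plec (plectin, a cytoskeletal linker), Macf1 (a microtubule and actin crosslinker), Peg3 (an imprinted zinc finger gene), Syne1 (a nuclear envelope spectrin-repeat protein), Spag9 (a kinase scaffold) and Kif5a (a neuronal kinesin). Without that limit, 30 genes had a peak in all 6 lists, and the first 10 by peak strength included Slc35e2b, Usp34, Nup153, Ank3, Plec, Myo9a, Syne1, Ubr4 and Zc3h13. Zc3h13 is part of the m6A writer complex.

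Of the 14 genes with a peak in all 6 lists under the limit, 6 shared a place in every list. The strongest Slc35e2b peak lay on the plus strand of chromosome 5 from 173046075 to 173046194 in 5 of 6 lists, and from 173046046 to 173046194 in bone cancer pain 2. Its fold enrichment was 88.2, 117 and 374 in controls 1, 2 and 3 and 286, 369 and 26.5 in bone cancer pain 1, 2 and 3. Slc35e2b was the only named gene among these 6. Another 6 segments recurred in 5 lists, among them segments of Hsp90ab1 (a cytosolic chaperone; chromosome 9, 17820325 to 17820624) and Usp34 (chromosome 14, 108143962 to 108144203). The segments were chosen after their values were seen. Of 10586 segments in total, 9984 occurred in a single list.

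The first comparison asked whether the number of called ac4C peaks differed in bone cancer pain. As deposited, the lists averaged 1476 ± 301 peaks in controls and 18002 ± 28079 in bone cancer pain (SD, n = 3 per group), and the exact permutation test on log2 numbers gave p = 0.4. Distinct genes averaged 1314 ± 235 and 10743 ± 15930 (SD, n = 3), also with an exact permutation p of 0.4. Bone cancer pain list 1 alone set the difference: it was 20.9 times as long as the next longest list, and 49281 of its peaks had the same fold of 10.6, a p-value of 0.0372 and an FDR of 0.0562. With an FDR of at most 0.05, the lists held 916, 1074 and 1003 peaks in controls and 919, 1240 and 899 in bone cancer pain, or 998 ± 79.1 and 1019 ± 191 (SD, n = 3; exact permutation p = 0.9). The smallest p that 3 against 3 allows is 0.10.

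**Figure D1:**
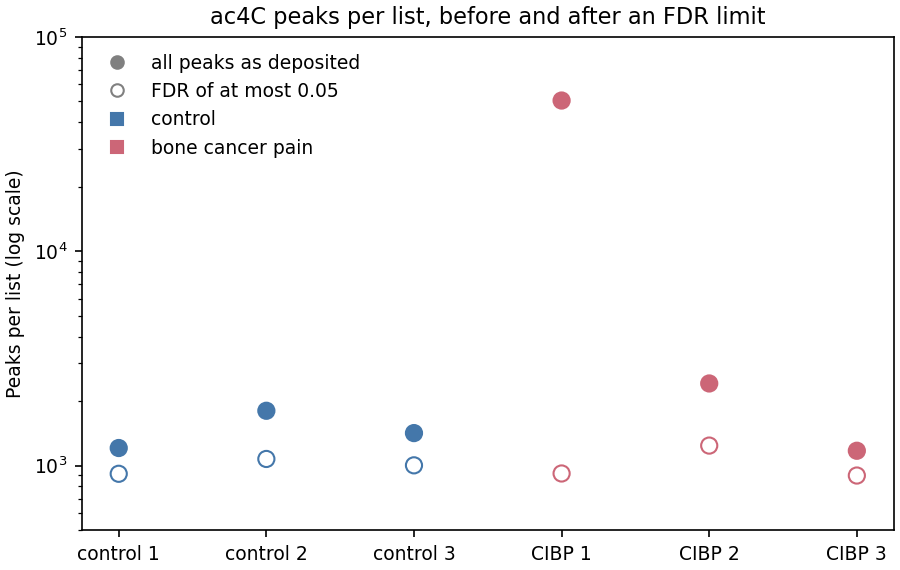
Number of ac4C peaks in each list on a log scale, for all deposited peaks (filled) and for peaks with an FDR of at most 0.05 (open), in control (blue) and bone cancer pain (CIBP, red) replicates. List 1 of bone cancer pain stands at 50417 peaks as deposited and at 919 under the limit, inside the range of the other lists.

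Peak strength and width did not separate the groups either. The median fold enrichment per list averaged 13.9 ± 2.48 in controls and 12.9 ± 4.13 in bone cancer pain (SD, n = 3; exact permutation p = 0.6). The median of -log10 of the p-value averaged 7.0 ± 3.75 and 5.65 ± 5.67 (SD, n = 3; exact permutation p = 0.5). The median exonic width was 180 bp in every list except bone cancer pain 1, where it was 361 bp. After Benjamini-Hochberg adjustment over these 5 measures, the smallest adjusted p was 0.75 in the exact permutation tests.

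Genes gained in bone cancer pain were led by Drp2, a dystrophin-related gene with a peak in 3 of 3 bone cancer pain lists and in 0 of 3 control lists. Its strongest peaks on chromosome X started at 105287776, 105286372 and 105287567 in bone cancer pain 1, 2 and 3, with folds of 63.5, 26.1 and 98.4. Next stood Fbxo18, an F-box DNA helicase, with folds of 26.5, 20.9 and 124, and Ttl, the tubulin tyrosine ligase, with folds of 10.6, 88.9 and 1400. Kdm2a (a histone demethylase), Fhl1, Npat, Ctsf (cathepsin F), Sirpa, Rap2a and Gprc5b completed the first 10, all with 3 lists against 0. The bone cancer pain 1 peaks of Ttl, Ctsf, Sirpa, Rap2a and Gprc5b were all at the recurrent fold of 10.6. The strongest bone cancer pain 2 peaks of Kdm2a, Fhl1 and Npat had an FDR of 0.127. Only Drp2 and Fbxo18 of these 10 genes kept 3 lists against 0 at an FDR of at most 0.05. In total 1322 genes were gained and 66 were lost as deposited, and 1156 of the gained genes owed their place in bone cancer pain list 1 to peaks with an FDR above 0.05.

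With an FDR of at most 0.05, 169 genes were gained and 158 were lost, and 130 of these gained and 38 of these lost genes were also called from the full lists. Leaving out single lists under the limit gave 49 to 219 gained and 53 to 200 lost genes, and all 10 splits of the lists gave at least as many in total as the real groups (327). The 9 named genes with 3 lists against 0 were Drp2, Fbxo18, Fam168a, Lrrc4b (a synaptic adhesion protein), Enpp4, Vps13c (a lipid transfer protein), Pnpla8 (a phospholipase), Zfp106 and Gdi2 (a regulator of Rab GTPases). The tenth by rank was Cpt1a, the carnitine palmitoyltransferase of fatty acid oxidation, with folds of 286 and 131 in bone cancer pain 1 and 2.

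Lost genes, with peaks called in the control lists alone, were led as deposited by Scn3b, the beta 3 subunit of voltage-gated sodium channels. Its strongest peaks lay on chromosome 8, with folds of 3.21, 13 and 100 in controls 1, 2 and 3. The chromatin remodeller Chd3, the adenylate kinase Ak5, the kinesin Kif21a, Tspyl1, the lysophosphatidic acid receptor Lpar1, the anchoring protein Akap6 and Prrc2b also had 3 control lists against 0, followed by Larp4b and Clk4 with 2 lists. With an FDR of at most 0.05, Ankib1, Tanc2 (a postsynaptic scaffold), Snrnp200 (a spliceosomal helicase), Chrna7 (the alpha 7 nicotinic receptor), Bag6, Kif21a, Ak5, Dmxl1, Pak1 (a p21-activated kinase) and Lpar1 led, each with 3 lists against 0. Chrna7 had folds of 16.0, 16.3 and 100 in controls 1, 2 and 3 on chromosome 1. Of the 158 genes lost under the limit, 110 had a peak with a higher FDR in bone cancer pain list 1.

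No single gene could pass a test, since Fisher's exact test gives p = 0.1 for 3 lists against 0 and p = 0.4 for 2 against 0. With at least 2 lists still required, gained genes fell from 1322 to 117 without bone cancer pain 1 and to 481 without bone cancer pain 2. Lost genes numbered 286 without bone cancer pain 1, 104 without bone cancer pain 2, and 36, 25 and 21 without controls 1, 2 and 3.

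Among the fixed gene lists, synaptic genes were the ones over-represented in bone cancer pain as deposited. Of 28 named genes of the postsynaptic density and synaptic vesicle, 15 had a peak in at least 2 bone cancer pain lists (odds ratio 4.20, Fisher's exact test, adjusted p = 0.00712), against 1 in at least 2 control lists (adjusted p = 1). Of all named genes, 21.6% had a peak in at least 2 bone cancer pain lists and 6.60% in at least 2 control lists. Fisher's exact test did not match genes on input signal. The difference between groups itself was not past a test. Members per list numbered 2, 9 and 7 in controls and 21, 15 and 6 in bone cancer pain (exact permutation p = 0.3). With an FDR of at most 0.05 the 5 members in at least 2 bone cancer pain lists gave an odds ratio of 5.26 and an adjusted Fisher's exact p of 0.0789. The call was also lost without bone cancer pain 1, without bone cancer pain 2, at equal list lengths and for peaks in all 3 lists. Under that limit Dlg4 (PSD-95) had a peak in 3 bone cancer pain lists and 1 control list, and Bsn (bassoon) in 2 and 0.

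Receptors and channels of pain transmission went both ways under the FDR limit. Gria4 and Grin1, subunits of AMPA and NMDA receptors, and Cacna1d (an L-type calcium channel) each had a peak in 2 bone cancer pain lists and 0 control lists. Scn3b and the potassium channel Kcnc1 had a peak in 2 control lists and 0 bone cancer pain lists, and Cacna2d2 in 3 control lists and 1 bone cancer pain list. The MAP kinases Mapk3 and Mapk9 were gained, as were Flt1 (a VEGF receptor) and Rpl15, while Ndufb9 of respiratory complex I was lost. The neurotrophin receptor genes Ntrk2 and Sort1 had a peak in 3 bone cancer pain lists and 1 control list each. Zc3h13 had the opposite pattern, 1 list against 3. Vegfa, the ligand of Flt1, had a peak in 1 bone cancer pain list, on chromosome 9 from 17350343 to 17353804 with a fold of 9.15. In the full lists only Mapk3, Rpl15 and Vegfa of these genes counted as gained, and only Scn3b and Ndufb9 as lost. Vegfa counted there only through a peak in bone cancer pain list 1 with an FDR above 0.05.

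Cell type markers showed no common direction under the same limit. Rbfox3 (NeuN) had a peak in 3 bone cancer pain lists and 1 control list, Elavl4 in 2 and 0, and Nefm, a neurofilament gene, in 0 and 2. Of the astrocyte genes, Slc1a3 was gained and Gja1 (connexin 43) was lost. Over all 35 lists, the smallest exact permutation p between groups was 0.1 as deposited (2 lists; adjusted p = 0.933) and 0.3 with the FDR limit (adjusted p = 1). As deposited, 31 lists had a higher mean number of members in bone cancer pain, against 16 higher, 11 lower and 8 equal under the limit.

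Replicates of the same group did not share more genes with an ac4C peak than replicates of different groups. With an FDR of at most 0.05, 134 to 210 genes were shared by each pair of lists, and shared genes made up 8.58% to 10.96% of the combined genes within groups and 8.27% to 11.7% between groups. The means were 9.53% within and 9.91% between groups. Of 3805 genes with a peak under that limit, 69.3% occurred in 1 list. For peaks as deposited, the mean share overlapped was 7.47% within and 7.17% between groups, and 4 of the 10 splits of the lists gave a within-group excess as large. Under the limit these shares were 3.92% and 4.16%.

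**Figure D2:**
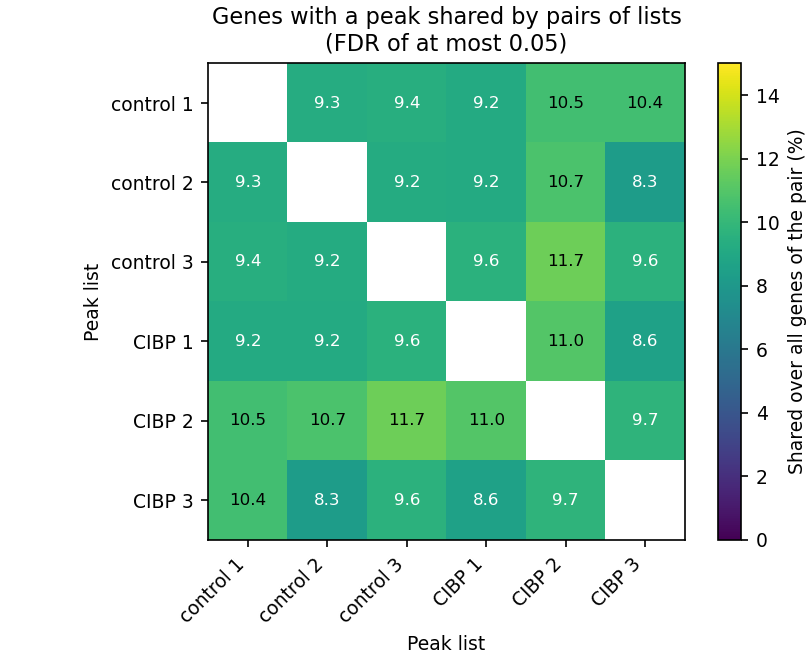
Genes shared by each pair of lists as a percentage of all genes of the pair, for peaks with an FDR of at most 0.05; both axes list the 3 control and 3 bone cancer pain (CIBP) lists. Values run from 8.27% to 11.7%, and pairs within a group do not exceed pairs between groups.

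In the RIP from bone cancer pain, oligodendrocyte and ribosomal protein genes had the highest medians among fixed lists with at least 10 genes, and calcium channel, synaptic and potassium channel genes the lowest. All values are from the authors' deposited table, in which the median gene had a log2 fold of 2.40. The 12 oligodendrocyte genes had a median of 3.13 in the authors' deposited table, with Cnp at 3.56, Opalin at 3.56 and Mbp (myelin basic protein) at 3.42. The 33 ribosomal protein genes had a median of 3.02, led by Rpl19 at 3.46. The 28 genes of the postsynaptic density and synaptic vesicle had a median of 1.90, with Vamp2 at 1.39, Syn1 at 1.51, Shank3 at 1.49 and Dlg4 at 1.76. The 16 calcium channel genes had a median of 1.86, with Cacna2d2 at 1.40, and the 16 potassium channel genes had a median of 2.01.

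Against random lists of like input signal, the oligodendrocyte and ribosomal protein lists both stood at the 100th percentile, and oxidative phosphorylation (20 genes, median 2.81, with Ndufb8 at 3.48) at 99.9. The synaptic list stood at percentile 0, the calcium channels at 0.020 and the potassium channels at 0.51. These 6 lists lay outside the central 95% in both IP and input pairs and under both ways of matching. Microglial genes (7 genes, median 2.92) stood at percentile 99.7, with Ctss at 3.26, C1qa at 3.21 and Cx3cr1 at 3.07 in the authors' deposited table, but at 97.1 in pair 1 alone. Of 31 lists with at least 3 genes, 5 lay above and 4 below the central 95%. For lists of unrelated genes 0.775 per side are expected, but members of these lists may vary together. The 2 further lists were the interferon response above (3 genes, median 2.98, percentile 97.6, but inside the central 95% at 97.4 when matched on all 4 libraries, and at 96.6 and 94.1 in pairs 1 and 2) and motor neurons below (4 genes, median 1.79, percentile 2.0, but 18.3 in pair 1). Transcript length, which differs between such groups, was not analysed here.

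**Figure D3:**
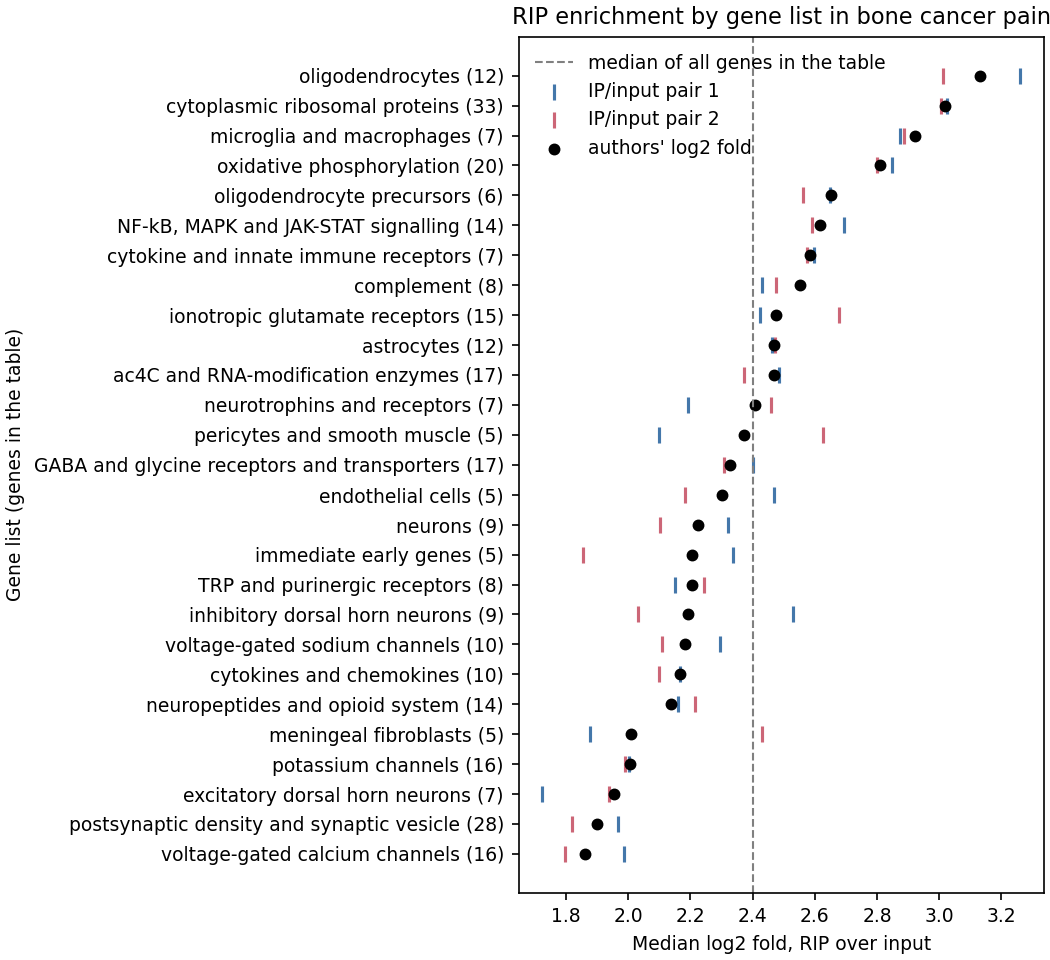
Median log2 fold of RIP over input for each fixed gene list with at least 5 genes in the table (gene number in brackets), from the authors' log2 fold (black) and from each IP and input pair (blue and red ticks); the dashed line is the median of all genes, 2.40. Oligodendrocyte genes lie at 3.13 and calcium channel genes at 1.86.

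The other lists lay inside the central 95% when matched on input signal. Excitatory dorsal horn neurons lay outside it, at percentile 1.9, when matched on all 4 libraries, and at 0.31 in pair 1; ionotropic glutamate receptors lay just above it in pair 2. Medians of the signalling and immune lists were 2.62 for NF-kB, MAPK and JAK-STAT signalling (14 genes), 2.59 for cytokine and innate immune receptors (7 genes), 2.55 for complement (8 genes), 2.76 for antigen presentation (3 genes) and 2.17 for cytokines and chemokines (10 genes, with Vegfa at 1.68). Among receptors and channels they were 2.48 for ionotropic glutamate receptors (15 genes), 2.33 for GABA and glycine receptors and transporters (17 genes), 2.18 for sodium channels (10 genes), 2.20 for TRP and purinergic receptors (8 genes), 2.14 for neuropeptides and the opioid system (14 genes) and 2.41 for neurotrophins and their receptors (7 genes). RNA-modification enzymes had a median of 2.47 (17 genes, with Thumpd1, a cofactor of RNA acetylation, at 2.02) and immediate early genes 2.20 (5 genes). The cell type lists gave 2.22 for neurons (9 genes), 1.96 for excitatory (7 genes) and 2.19 for inhibitory (9 genes) dorsal horn neurons, 2.47 for astrocytes (12 genes), 2.65 for oligodendrocyte precursors (6 genes), 2.30 for endothelial cells (5 genes), 2.37 for pericytes and smooth muscle (5 genes), 2.01 for meningeal fibroblasts (5 genes) and 2.19 for Schwann cells and sensory ganglia (4 genes). Ependymal, blood, and muscle and bone lists had 1, 2 and 1 genes in the table. Of the mitochondrially encoded list 0 genes were matched by symbol, although the table held 2 mitochondrial rRNA genes.

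Single genes with the smallest FDR in the authors' deposited table were Trak2, a motor adaptor of mitochondrial transport (log2 fold 3.55), Plekhb1 (3.28), Pea15 (3.04), S100b (2.97), Zeb2 (3.08), the sterol synthesis genes Cyp51 (3.46) and Hmgcs1 (3.02), the myelin genes Mal (3.26) and Ugt8 (3.69), and Usp9x (2.87). The largest folds among genes above the median of mean signal, which includes the IP libraries, included small RNAs: SNORA63 at 5.78, U5 at 5.06, Y_RNA at 4.82, 2 SNORD115 genes at 4.17 and 4.08, and SNORD17 at 3.94. Protein-coding genes among those 10 were Prdx4 at 4.23, Borcs8 at 3.89, Ncmap (a myelin-associated gene) at 3.88 and S100a1 at 3.83. Mean input signal was only 1.06 for SNORA63 and 1.24 for Prdx4, near the lowest input value of the table (1.00), so these folds rest on very little input. Such small RNAs belong to families of near-identical copies, so reads may be split between copies and their values are uncertain. Mean signal of the Y_RNA gene was 512 in input and 14487 in IP, and that of Mbp was 1061 and 11314 (n = 2 each).

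All 8671 RIP genes had a higher signal in IP than in input in both pairs, and 8560 had a log2 fold above 1 in each; the authors' threshold on the same libraries largely fixed this. The median log2 fold was 2.45 in pair 1 and 2.37 in pair 2, and the median SD between pairs was 0.17 per gene. Across genes, which are not independent replicates, the folds of the pairs had a Pearson r of 0.646 and a Spearman rho of 0.655. Of all genes, 95.7% lay within 1 log2 unit of the median, and 6 had an FDR above 0.05 in the authors' deposited table. Summed over the listed genes, IP signal was 5.78 times input signal in pair 1 and 5.56 times in pair 2. Without counts of all genes, a difference in scale between IP and input values cannot be told apart from precipitation.

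Most genes with a firm ac4C peak were in the RIP table. Of 378 genes with a peak in at least 2 bone cancer pain lists at an FDR of at most 0.05, 347 (91.8%) were in the table; every gene named here is among them by construction, since names came from that table. The share was 93.4% of 361 genes for the controls, 92.3% of the 169 gained genes and 93.7% of the 158 lost genes. As deposited, 1875 of 2314 genes (81.0%) in at least 2 bone cancer pain lists were in the table, against 26.1% of the 29990 genes with a peak in any list (odds ratio 15.6 by Fisher's exact test). That background came almost wholly from bone cancer pain list 1. No gene of the RIP table had an input value below 1.00, so membership itself depended on expression. Fisher's exact tests of this overlap did not match genes on input signal. Among the 3805 genes with a peak at an FDR of at most 0.05, of which 84.0% were in the table, the log2 odds ratio of the 378 genes was 1.19 (Fisher's exact p = 4.0e-06), against 5.05 for the same genes in the full background.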

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

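Every alternative with the FDR limit of at most 0.05 and the ranking behind equal lengths were chosen after seeing the data; the other alternatives were fixed before. No paired test changed a call: with a replicate block, the log2 differences stayed at 1.84 for peaks and 1.62 for genes, with sign-flip permutation p of 0.5 for both, where 0.25 is the smallest possible. Deviations of same-numbered lists correlated at only 0.054, 0.022 and 0.024 as deposited, which cannot show whether replicate numbers pair the replicates. Every list correlated best with its own number there, a hint that was gone with the FDR limit (-0.0086, 0.0036 and -0.0063).

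The higher number of peaks in bone cancer pain fell from a log2 difference of 1.84 to 0.018 with the FDR limit; leaving out lists gave 0.21 to 2.92 as deposited and -0.13 to 0.10 with the limit. For genes the ranges were 0.18 to 2.56 and -0.088 to 0.11. The median fold changed sign from -0.13 to 0.28 with the FDR limit, to 0.042 at a fold of at least 4 and to 0.30 at equal lengths, and ran from -0.38 to 0.0053 and from 0.076 to 0.46 without single lists. The median -log10 p changed sign from -0.71 to 0.045 with the limit, with ranges of -1.53 to 0.013 and -0.41 to 0.40. The width difference of 0.33 ran from 0 to 0.50 and from 0 to 0.0040. The FDR limit and equal lengths removed weak peaks from several lists, and the weak peaks of bone cancer pain list 1 were not removed alone, so the cause was not tested further.

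Gained genes moved from 1322 to 169 with the FDR limit, 191 at equal lengths, 94 at 3 of 3 against 0 and 9 with both, and ran from 117 to 1604 without single lists and from 49 to 219 with the limit. Lost genes moved from 66 to 158, 192, 8 and 11 in that order, and to 188 for merged regions, with ranges of 21 to 286 and 53 to 200. The within-group excess of peak overlap turned from 0.29 percentage points to -0.25 with the limit and -0.14 at equal lengths, with ranges of -1.97 to 2.06 and -0.33 to -0.18. The 1 gene list over-represented in bone cancer pain became 0 with the limit, at equal lengths and for peaks in all 3 lists, and 0 to 1 without single lists. In controls 0 lists were over-represented as deposited, but 1 was at equal lengths and 1 at a fold of at least 4. The log2 odds ratio of RIP genes turned from 3.96 to -5.64 for genes in any bone cancer pain list, which by construction take up nearly the whole background. Its other alternatives kept direction and call. The RIP table's alternatives (6867 to 8663 genes) could not lose direction, since the table holds only genes past the authors' threshold.

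Not run were exon-only peaks, location, motif, a background of annotated or unlisted genes, genes of like length, DESeq2 on the RIP and an unfiltered RIP table, which need an annotation, names, or counts of all genes. A block does not apply to counts of gained and lost genes. Without read depth, a gene lacking a peak cannot be told from a gene with too few reads.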

Other observations

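Tests chosen after the result was seen were those of the long list, of unrelated draws and of the splits of the lists; the tests of peak strength, of expression level and of RIP strength were set before, though the matching of the last was changed after its result was seen. The interferon gene Ifi27 (log2 fold 3.31 in the authors' deposited table), the prostaglandin synthase Ptgds (3.49) and the glial potassium channel Kcnj10 (3.01) stood high in the RIP of bone cancer pain, while Col3a1 (1.08), a collagen gene of meningeal fibroblasts, stood low; these genes were picked after their values were seen. By class of RNA, 9 snRNA genes had a median log2 fold of 3.01, 56 snoRNA genes 2.55 and 31 lincRNA genes 1.94, against 2.40 for 8420 protein-coding genes. Both mitochondrial rRNA genes differed between pairs, with median log2 folds of 1.29 in pair 1 and 2.78 in pair 2.

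The ac4C list of bone cancer pain replicate 1 was 20.9 times as long as the next. Against a rise of that size in acetylated RNA throughout bone cancer pain, lists 2 and 3 of that group held only 2416 and 1173 peaks as deposited. The controls held 1208, 1802 and 1418. A smaller rise stays open. At an FDR of at most 0.05, bone cancer pain list 1 held 919 peaks, inside the control range of 916 to 1074. The other bone cancer pain lists lay above and below that range, at 1240 and 899. A candidate explanation is a shallow IP library in which windows with single reads passed the caller's threshold. In bone cancer pain list 1, 97.7% of the peaks sat on a fold of 10.6 (deposited p-value 0.0372), which may be 1 step of whole reads. The commonest fold of the other lists may be 2 steps of 5.25 to 8.85. This reading is uncertain, since 42 peaks of bone cancer pain list 1 lay at 0.5 and 40 at 1.5 times its commonest fold. If it holds and reads are independent, 1 step would give p of 0.0462 to 0.0933 there, above the largest p in any list, 0.0407; read totals that could settle this were not used here.

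Genes with a peak differed between replicates of 1 group as much as between groups. Within the genes of the RIP table, the only ones with an input signal, unrelated draws are argued against, because every pair of lists shared at least 1.59 times the genes expected from deciles of that signal. Weak peaks near the calling threshold may contribute: with the genes of each list divided by peak strength into 3 equal parts, the strongest part recurred in another list 10.8 percentage points more often than the weakest (median of 6 lists), between the limits of 10 and 20 set beforehand, so this stays open. The real grouping gave 1388 gained and lost genes as deposited, where 4 of 10 splits gave as many and the highest other gave 1746; with the FDR limit it gave 327, where all 10 splits gave as many and the highest other gave 371. With 10 splits no share can fall under 0.05.

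Most genes with a firm peak were in the RIP table. Whether acetylated RNAs are precipitated more strongly in the RIP stays open: the 347 genes with a peak in at least 2 bone cancer pain lists had a median log2 fold of 2.44, at percentile 87.5 of random lists matched on input signal, above their median of 2.40 but inside the central 95%. The bound set beforehand took any such value as evidence against, which was wrong because it lies within the spread of random lists. The 3195 genes with a peak in any list stood at percentile 100, although their median was 2.44 against 2.40 for random lists. Genes with a peak in at least 2 control lists stood at percentile 89.0 in the same matching. Matched on the mean of all 4 libraries, which contains the IP signal, the 347 genes stood at 0.915 and the 3195 genes at 0.855. Expression level may link both sets, since the share of RIP genes with a peak was 59.5% in the top and 19.6% in the bottom decile of input signal, a ratio of 3.04 (95% interval 2.63 to 3.53 from binomial resampling), narrowly past the limit of 3 set beforehand; genes outside the RIP table could not be tested.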
